A study of Mus musculus with 5 samples.

How the data were processed

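RNA was sequenced from uveal tissue of adult wild-type mice (2 libraries) and from eye tumors of adult mice with floxed Lats1 and Lats2 alleles and virally delivered Cre recombinase (3 libraries). Per the labels' protocols, the tissue was frozen on dry ice, RNA was extracted with Trizol and libraries were made with an Illumina TruSeq RNA kit. Per the submitters' processing notes, TopHat2 2.0.9, Cufflinks 2.2.1 and Cuffdiff were used with the mouse genome build mm10. The role of each tool, the gene annotation, the read filters and the strand setting are not given in the sources used here. Reads of a gene and of an overlapping or antisense gene can therefore not be told apart.

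The deposited table per replicate holds 24768 loci. It gives an estimated count of fragments that the authors did not scale, and an FPKM (fragments scaled for transcript length and sequencing depth) that follows the authors' scaling between libraries, per the file headers. The scaling factors behind the FPKM were 1.00 and 0.931 for the wild-type libraries and 1.06, 1.05 and 0.997 for the tumor libraries. Of the estimated counts, 96.8% to 97.1% per library were whole numbers and 98.6% to 98.7% lay within 0.01 of one. All were rounded to whole numbers before the count tests. An estimate was marked as failed for 3 values, which were used as they stand. The deposited FPKM per group was within 1% of the mean of the replicates at 100% of the loci above 1 FPKM (14457 in tumors, 14262 in wild type), so the replicate values alone were analysed. The authors' group counts were not used, since they are means of values in the replicate table.

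The condition name in the table gives each library's group. Its replicate numbers start at 0 and those of the labels at 1, and nothing ties the series of numbers together, so the numbers only name libraries of a group. Libraries are called wild-type library 1 and 2 and tumor library 1, 2 and 3 in the table's order. Before averaging, libraries were compared over loci with at least 20 fragments in the pair. The wild-type pair differed by a chi-square of 5.43 per degree of freedom and the tumor pairs by 102 to 129, so each pair differed by more than sampling noise and all 5 libraries were kept.

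Loci without a gene name (1627 of 24768) stayed out of library sizes and tests. They held 2.78% and 2.85% of fragments in the wild-type libraries and 4.37%, 1.96% and 1.52% in tumor libraries 1, 2 and 3. A locus can hold several genes: 384 loci carried more than 1 name and held 2.93% to 4.20% of fragments. The 23141 named loci entered edgeR 4.0.16 under R 4.3.3. Loci were kept by filterByExpr at its default minimum count of 10, libraries were scaled by TMM (factors 0.982 and 1.00 in wild type, 1.04, 1.08 and 0.909 in tumors), and the quasi-likelihood F-test compared tumor with wild type over all 5 libraries without a covariate. P-values were two-sided and adjusted by the Benjamini-Hochberg method. An adjusted p under 0.05 counted as a change, and "rose" and "fell" are used only of loci past it. Unless another tool is named, adjusted p-values of genes are from edgeR. A standard error (SE) of a log2 fold change is the fold change divided by the square root of the F statistic. Gene levels are FPKM with the SD over libraries, and log2 fold changes are edgeR values of tumor over wild type. A fold against a group at 0 in all libraries was computed against a floor of 3 counts per library, a lower bound that covers counting error only.

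Before the data were examined, 28 gene lists were fixed from general knowledge. They hold YAP/TAZ-TEAD targets, Hippo pathway components, pigment genes, markers of the cell types that an eye or a tumor can hold, and genes of interferon response, proliferation, epithelial-mesenchymal transition, metabolism, hypoxia, stress, G alpha q signalling and human uveal melanoma classes. Genes were matched by exact symbol, older or newer, and a locus shared by members of a list counted once. Lists with at least 4 tested members (26) were compared with all other tested loci by camera (limma 3.58.1) on log2 CPM with a prior count of 2 and a preset correlation of 0.01 between genes. The p-values were adjusted over the 26 lists, and the p given for a list is from camera unless another test is named. Camera was repeated with a correlation estimated for each list. The test fry asks whether the genes of a list move, on balance, in 1 direction, and does not compare them with other genes. Hemoglobin genes (3 loci) and sex-linked genes were described by their values. Mmp9 and Cdh1 stood in 2 lists each.

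The genes named in the text follow a rule fixed at the same time. They are Lats1 and Lats2, 12 fixed genes, and the 6 largest rises and 6 largest falls among changed loci with a mean of at least 10 FPKM in the higher group, groups that do not overlap and a single name that is not that of a predicted gene, small RNA or ribosomal pseudogene. To these come, for each list, up to 2 changed members with the smallest p in the direction taken by more members and up to 1 in the other. Some genes that the rule selects are not reported here. Genes named outside the rule are given as chosen after their values were seen.

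The alternatives fixed in advance were RLE factors, upper quartile factors, library size alone, TMM without the genes of the eye and muscle lists, no filter on low counts, a minimum count of 50, DESeq2 1.42.0, limma-trend on log2(FPKM + 1) with a filter (at least 1 FPKM in at least 2 libraries) and without one, limma-trend on log2(FPKM + 0.1), robust dispersion, a replicate block, each library left out in turn, an adjusted p under 0.01, and glmTreat at a log2 fold of 1. For the lists they were an estimated correlation, fry, and lists without shared genes. Voom with a weight per group, unnamed loci kept, and DESeq2 without either wild-type library were chosen after seeing the data. Locus starts were checked against GENCODE M21: 4.20% matched an exon start as they stand and 40.7% after adding 1, so 1 was added and all coordinates count from 1.

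The test was tried on simulated counts for the comparison of tumor with wild type, over 15006 loci with the means, library sizes and dispersions fitted to these data and 50 loci changed at each size. It recovered 0% of the loci changed 1.5-fold, 0% of those changed 2-fold, 20% of those changed 4-fold and 64% of those changed 8-fold. It made 42 calls, 0% of them false. Camera called a simulated list of 15 genes shifted 8-fold and 0 of 25 unchanged lists, and camera with an estimated correlation did not call the shifted list. The simulation used the same dispersion in both groups, whereas the tumor libraries varied more than the wild-type ones. It also changed far fewer loci than the 5201 called in the data, which makes the adjusted threshold stricter. The recovered shares therefore do not give the power of the test on these data. Simulated genes were drawn independently, so the simulation cannot show how often camera calls unchanged lists of correlated genes. Depth ranged from 12687700 to 14368274 estimated fragments per library. With 2 against 3 libraries an exact permutation test of a single value cannot go below p = 0.1, so single values were tested only within the models over all loci. Tables were prepared with Python 3.11.15 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.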

Results

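The transcriptome of eye tumors with targeted deletion of the Hippo pathway kinase genes Lats1 and Lats2 was compared with that of wild-type uvea, the pigmented middle layer of the eye made up of iris, ciliary body and choroid. These kinases phosphorylate the coactivators YAP and TAZ and so keep them out of the nucleus. The tumors arose in adult mice with floxed alleles of both genes after an adeno-associated virus of serotype 5 brought in Cre recombinase, and the series title calls them uveal melanoma. The wild-type group had 2 libraries with 13911932 and 12799990 estimated fragments, and the tumor group had 3 with 13745769, 12687700 and 14368274. Nothing in the labels says that libraries of a group came from separate animals, so p-values measure only the spread between these samples, part of which may be technical.

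The wild-type libraries were close to each other (Spearman correlation across 14548 loci 0.996), and the tumor libraries less so (0.907 to 0.915). The median SD of log2 CPM between libraries was 0.088 in wild type and 0.343 in tumors. The first principal component held 78.4% of the variance and separated the groups. Sex-linked transcripts differed between libraries: Xist, made from the inactive X chromosome, was at 3.30 and 3.05 FPKM in wild type and at 0.00792, 0.00803 and 22.6 FPKM in tumor libraries 1, 2 and 3. The Y-linked gene Ddx3y was at 8.60 and 10.7 FPKM in wild type and at 21.3, 14.6 and 0 FPKM in the tumors. Both wild-type libraries thus held transcripts of both kinds, and each tumor library was high in a single kind. None of the 5 sex-linked loci passed the test. The labels do not say whether a library holds RNA of 1 animal or of several. Transcripts of both kinds in each wild-type library argue against RNA of 1 animal there. Pooling would narrow the spread between libraries on which the p-values rest.

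Lats1, the first of the targeted genes, fell in the tumors. It lies on chromosome 10 from 7678971 to 7716461 (mm10, plus strand), a protein-coding gene of 8 exons, and its level was 8.20 ± 0.927 FPKM in wild type (SD, n = 2) and 3.42 ± 0.481 FPKM in tumors (SD, n = 3). Its log2 fold change was −1.21 (SE 0.18, edgeR adjusted p = 0.012), and all 3 tumor libraries, at 3.43, 3.90 and 2.94 FPKM, lay below both wild-type libraries at 7.55 and 8.86 FPKM. With wild-type library 1 or 2 left out, its log2 fold changes were −1.37 and −1.13, and Lats1 did not pass in edgeR. In those fits the spread between tumors alone sets the error, so the lost call is not particular to Lats1. Over all 5 libraries with DESeq2, Lats1 passed at −1.25 (adjusted p = 1.3e-06). Lats2 lies on chromosome 14 from 57689564 to 57746126 (minus strand, 8 exons). Its level was 20.1 ± 0.125 FPKM in wild type (SD, n = 2) and 14.7 ± 2.21 FPKM in tumors (SD, n = 3), a log2 fold change of −0.62 (SE 0.19) that did not pass the test (edgeR adjusted p = 0.058). Without tumor library 2, Lats2 passed at −0.81 (edgeR adjusted p = 0.017), and with DESeq2 it passed at −0.66 (adjusted p = 0.015). These gene-level values can include exons outside the deleted part and RNA of cells that did not recombine, and neither share was measured. They therefore cannot measure how complete the deletion was.

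**Figure D1:**
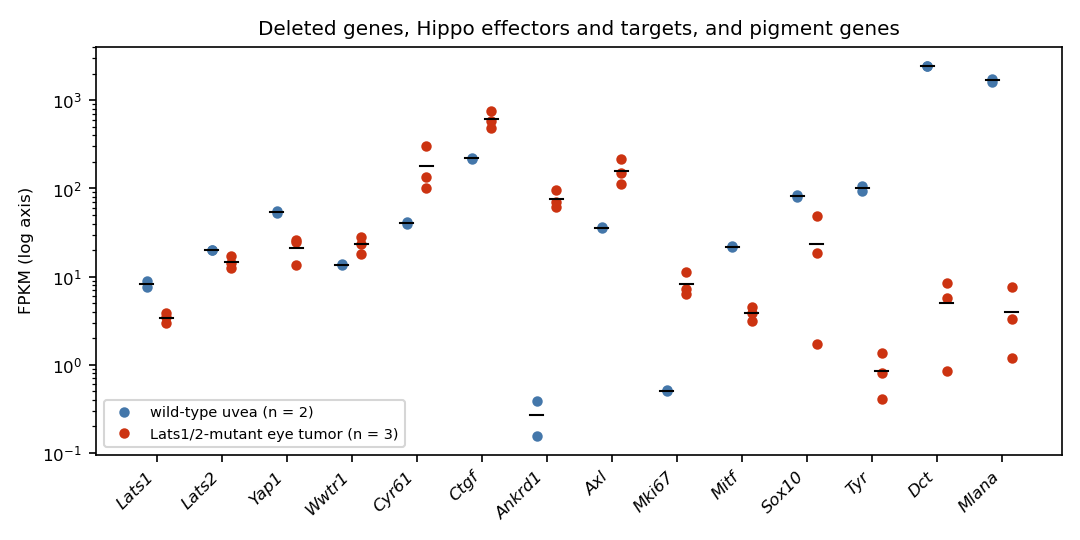
FPKM of 14 genes on a log axis in the 2 wild-type libraries (blue) and the 3 tumor libraries (red), with each group's mean as a black line. Ankrd1 lies at a mean of 0.268 FPKM in wild type and 75.9 FPKM in tumors, and Dct at 2460 and 5.05 FPKM.

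The tumors differed from wild-type uvea at 5201 of 15241 tested loci (34.1%), of which 2852 rose and 2349 fell. Past a log2 fold change of 1 there were 2204 rises and 1773 falls. The largest rises were led by H28, a minor histocompatibility antigen gene. It was at 0 in both wild-type libraries and at 14.2 ± 3.87 FPKM in tumors (SD, n = 3), at least 68.3-fold higher. Ankrd1, a classical YAP target, rose from 0.268 ± 0.161 to 75.9 ± 18.1 FPKM, a log2 fold change of 8.15 (SE 0.50, adjusted p = 0.0033). Gbp1, an interferon-induced GTPase with close paralogs among which reads may be split, rose by 9.21 (adjusted p = 0.012). Msln, which encodes the surface protein mesothelin, rose by 7.66 (adjusted p = 0.0038). Tnnt2, the troponin T of heart muscle, rose by 7.68 (adjusted p = 0.022) and was at 19.9, 2.71 and 8.35 FPKM in tumor libraries 1, 2 and 3.

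The largest falls held genes of light-sensing cells and of pigment granules. Gip, which encodes a peptide hormone, was at 38.8 ± 4.04 FPKM in wild type (SD, n = 2) and at 0 in all 3 tumor libraries, at least 90.7-fold lower. The homeobox gene Gsx2 went from 50.1 to 0.0332 FPKM, a log2 fold change of −10.27 (SE 0.47, adjusted p = 0.0029). Pdc (phosducin) had a log2 fold change of −9.85 (adjusted p = 0.0029) and the rod exchanger gene Slc24a1 of −9.55 (adjusted p = 0.0049). Tumor counts were 1, 0 and 1 for Gsx2 and 0, 1 and 2 for Pdc, so the sizes of these folds are uncertain and not comparable with the bound for Gip. Pmel, which forms the fibrils of pigment granules, went from 1400 ± 54.5 to 1.54 ± 0.717 FPKM, a log2 fold change of −9.77 (SE 0.54, adjusted p = 0.0029).

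At all 5201 changed loci the groups did not overlap. Among tested loci 70.0% did not overlap, against 20% by chance with 2 and 3 libraries. Without wild-type library 1 or 2, edgeR called 0 loci (unadjusted p under 0.05 at 4085 and 3996 loci), with the remaining library assumed to vary like the tumors, so every count of changed list members was also 0 in those fits. DESeq2 called 2840 and 2794 loci in the same sets. Of the changed loci 54.8% were higher in tumors, and this share was 44.2% with limma-trend on log2(FPKM + 1) without a filter.

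The YAP/TAZ-TEAD targets and the Hippo pathway components were examined first, as the readout of the deleted kinases. Of 21 YAP/TAZ-TEAD targets 10 rose, 3 fell and 8 did not pass (11 rose and 3 fell adjusted over the list alone). Besides Ankrd1, the secreted matrix proteins Cyr61 and Ctgf rose by 2.19 (SE 0.55, adjusted p = 0.038) and 1.53 (SE 0.28, adjusted p = 0.018), to 180 ± 108 and 612 ± 140 FPKM in tumors (SD, n = 3). The receptor kinase gene Axl rose by 2.2 (adjusted p = 0.014) and the stress gene Gadd45b by 3.12 (adjusted p = 0.003). The targets that fell were Dock5 (log2 fold change −1.71, adjusted p = 0.017) and, chosen after their values were seen, Crim1 (−2.2, adjusted p = 0.018) and Nt5e (−1.92, adjusted p = 0.029). The median log2 fold change of the list was 1.45, against 0.048 over all tested loci. Among all 15241 tested loci 2852 rose and 2349 fell. Camera did not call the list (adjusted p = 0.0942), which does not show that its genes moved as other genes did. Fry called it (adjusted p = 0.0186), as did camera without tumor library 1 (adjusted p = 0.0256), and it had 5 falls without tumor library 2 and 6 with voom, a setting chosen after the results were seen.

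Yap1, which encodes the coactivator itself, fell from 54.0 ± 2.32 to 21.3 ± 6.69 FPKM (log2 fold change −1.29, SE 0.31, adjusted p = 0.035), while Wwtr1, which encodes TAZ, rose by 0.82 (SE 0.23, adjusted p = 0.049). Of 25 other Hippo pathway components, these genes included, 10 rose, 2 fell and 13 did not pass (11 and 2 adjusted over the list alone). The scaffold gene Rassf1 rose by 2.16 (adjusted p = 0.0039) and Frmd6 by 1.84 (adjusted p = 0.0057), and the atypical cadherin gene Dchs1 had a log2 fold change of −1.22 (adjusted p = 0.033). The list's median was 0.53 and camera did not call it (adjusted p = 0.126), whereas fry did (adjusted p = 0.0186). The Wwtr1 call ended in 10 other settings (adjusted p = 0.05 to 0.081) and without tumor library 1 or 2 (adjusted p = 0.09 and 0.076). Without tumor library 1 those of Yap1 (adjusted p = 0.062) and Dchs1 (adjusted p = 0.078) ended as well, leaving 0 falls, and library size alone ended them too (adjusted p = 0.06 and 0.057); there were 4 falls without tumor library 2 and 5 each with DESeq2 and voom.

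Pigment genes were far lower in the tumors. Of 20 melanocyte and pigment genes 17 fell and 0 rose (the same counts adjusted over the list alone), with a median log2 fold change of −6.16 (adjusted p = 2.29e-09; adjusted p = 0.436 with an estimated correlation). Tyr, the first enzyme of melanin synthesis, went from 99.9 ± 8.04 to 0.852 ± 0.475 FPKM (log2 fold change −6.93, SE 0.58, adjusted p = 0.0049). Dct, a further enzyme of the pathway, had a log2 fold change of −8.88 (adjusted p = 0.0091) and the melanosome gene Mlana one of −8.74 (adjusted p = 0.0048). Mitf, the transcription factor that drives these genes, fell less, by 2.42 (SE 0.19, adjusted p = 0.0044). Sox10, a neural crest factor, was at 84.3 and 79.3 FPKM in wild type and at 18.5, 49.1 and 1.73 FPKM in the tumors. Its log2 fold change of −1.77 (SE 1.18) did not pass (adjusted p = 0.29).

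Markers of the retinal pigment epithelium and of photoreceptors were lower to a similar size. Of 12 markers of the retinal pigment epithelium, the cell layer behind the retina, 11 fell and 0 rose (likewise adjusted over the list alone), with a median of −7.24 (adjusted p = 3.57e-06; adjusted p = 0.417 with an estimated correlation). The vitamin A receptor gene Stra6 had a log2 fold change of −7.29 (adjusted p = 0.0034), and the locus that holds both Bloc1s1 and the retinoid enzyme gene Rdh5 one of −4.95 (adjusted p = 0.0029). Of 20 photoreceptor markers 19 fell and 0 rose (20 and 0 adjusted over the list alone), with a median of −6.46 (adjusted p = 1.8e-10; adjusted p = 0.417 with an estimated correlation). Sag (arrestin) and Pde6g (phosphodiesterase) had log2 fold changes of −6.84 (adjusted p = 0.0029) and −7.53 (adjusted p = 0.0033).

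Inner retina and lens markers differed among the tumors. Of 18 tested inner retina and Muller glia markers 4 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of −1.41 (adjusted p = 0.00681; adjusted p = 0.715 with an estimated correlation). Slc6a9, a glycine transporter gene, had a log2 fold change of −5.24 (adjusted p = 0.0083) and Glul, the glutamine synthetase gene, one of −2.87 (adjusted p = 0.0098), while the glial potassium channel gene Kcnj10 rose by 2.54 (adjusted p = 0.029). Of 16 tested lens markers 6 fell and 0 rose (the same adjusted over the list alone), with a median of −3.29 (adjusted p = 3.66e-06; adjusted p = 0.417 with an estimated correlation). Bfsp2 and Lim2, a filament and a membrane protein gene of lens fibers, had log2 fold changes of −6.11 (adjusted p = 0.005) and −7.89 (adjusted p = 0.0084). Tumor counts of Lim2 were 0, 2 and 0, so the size of its fold is uncertain. Tumor library 2 held more of both lists than the other tumors did, by 3.06 and 2.62 in median log2 CPM. It also held more of the retinal pigment epithelium, pigment and photoreceptor lists, by 2.27, 1.79 and 1.17. Without it 13 inner retina markers fell (median −3.60, adjusted p = 4.51e-06) and 11 of 15 tested lens markers did (median −6.54). Over all 5 libraries, voom called 8 falls in the inner retina list (median −2.86) and 10 in the lens list, and fry did not call the inner retina list (adjusted p = 0.127).

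**Figure D2:**
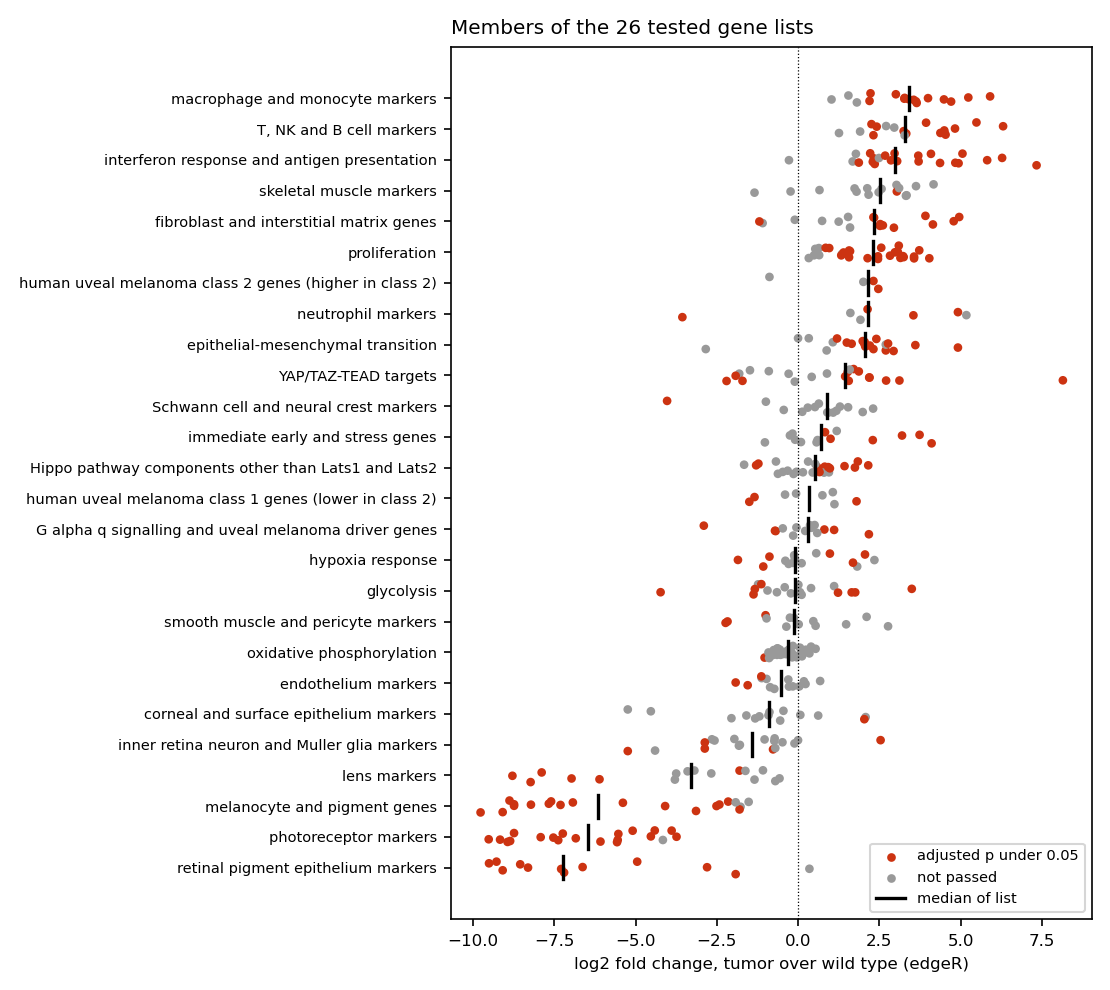
Log2 fold change of tumor over wild type (edgeR) for each tested member of 26 gene lists, with members past an adjusted p of 0.05 in red, others in gray and the list's median as a black line. Medians run from −7.24 in the retinal pigment epithelium list to 3.40 in the macrophage and monocyte list.

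Most leukocyte genes rose in the tumors. Of 17 macrophage and monocyte markers 14 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 3.40 (adjusted p = 7.85e-07; adjusted p = 0.533 with an estimated correlation). The antibody receptor gene Fcgr1 rose from 1.89 ± 0.0137 to 48.1 ± 15.3 FPKM (log2 fold change 4.71, adjusted p = 0.0045), and Cd14, the endotoxin co-receptor gene, rose by 4 (adjusted p = 0.0068). Of 18 tested T, NK and B cell markers 13 rose and 0 fell (16 and 0 adjusted over the list alone), with a median of 3.31 (adjusted p = 3.57e-06; adjusted p = 0.492 with an estimated correlation). The T cell genes Cd3g and Cd2 rose by 4.38 (adjusted p = 0.0085) and 3.94 (adjusted p = 0.014). Of 7 tested neutrophil markers 3 rose and 1 fell (5 and 1 adjusted over the list alone), and the list did not pass (median 2.14, adjusted p = 0.0944) except by fry (adjusted p = 0.00934) and with DESeq2 without wild-type library 1 (adjusted p = 0.0084). Csf3r and S100a8 rose by 3.55 (adjusted p = 0.0088) and 2.14 (adjusted p = 0.03), Camp had a log2 fold change of −3.56 (adjusted p = 0.018), and the S100a8 call ended without tumor library 1 (adjusted p = 0.05). With DESeq2, 5 neutrophil markers rose.

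Interferon response and antigen presentation genes moved with them. Of 23 such genes 19 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 2.97 (adjusted p = 4.3e-09; adjusted p = 0.436 with an estimated correlation). Oas1a, an antiviral enzyme gene, rose from 1.84 ± 0.147 to 23.5 ± 1.21 FPKM (log2 fold change 3.71, SE 0.18, adjusted p = 0.0029), and Irf7, a transcription factor gene of the interferon response, rose by 3.70 (adjusted p = 0.0043). Tumor library 3 was above the mean of the other tumors by 1.46 in the list's median log2 CPM and by 1.44 in that of the T, NK and B cell list. Without tumor library 2, 1 of the 23 genes fell.

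Most proliferation genes rose in the tumors. Of 28 such genes 22 rose and 0 fell (24 and 0 adjusted over the list alone), with a median of 2.30 (adjusted p = 7e-09; adjusted p = 0.533 with an estimated correlation). Mki67, which encodes the cell cycle antigen Ki-67, rose from 0.507 ± 0.0145 to 8.27 ± 2.56 FPKM (log2 fold change 4.04, SE 0.35, adjusted p = 0.0051). Top2a, the topoisomerase gene of dividing cells, rose by 3.23 (adjusted p = 0.0083).

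Most matrix and mesenchymal genes rose as well. Of 17 fibroblast and interstitial matrix genes 10 rose and 1 fell (13 and 2 adjusted over the list alone), with a median of 2.34 (adjusted p = 0.000569; adjusted p = 0.417 with an estimated correlation). The fibrillar collagen genes Col5a2 and Col3a1 rose by 4.79 (adjusted p = 0.0039) and 4.15 (adjusted p = 0.0076), the latter to 669 ± 267 FPKM in tumors (SD, n = 3). Fap, a protease gene of activated fibroblasts, had a log2 fold change of −1.19 (adjusted p = 0.034), a call that ended without tumor library 2 (adjusted p = 0.062) or 3 (adjusted p = 0.056), whereas 2 genes fell without tumor library 1 and with DESeq2 or voom. Of 21 genes of epithelial-mesenchymal transition 15 rose and 0 fell (15 and 1 adjusted over the list alone), with a median of 2.05 (adjusted p = 8.36e-06; adjusted p = 0.417 with an estimated correlation). The transcription factor gene Twist1 rose by 2.94 (SE 0.18, adjusted p = 0.0033) and Loxl2, a collagen crosslinking enzyme gene, by 2.77 (SE 0.18, adjusted p = 0.0034), and 1 gene of the list fell without tumor library 2 and with DESeq2 or voom.

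Muscle and epithelial markers set single tumors apart. The skeletal muscle list had a median log2 CPM of 6.18 and 6.13 in wild type and of 9.92, 6.02 and 5.72 in tumor libraries 1, 2 and 3. Acta1, the skeletal muscle actin gene, chosen after its values were seen, was at 99.8 and 89.5 FPKM in wild type and at 1925, 126 and 191 FPKM in the tumors. Of 16 tested skeletal muscle markers 1 rose and 0 fell (0 and 0 adjusted over the list alone; median 2.52, adjusted p = 0.382), the 1 being the myosin gene Myh2 (log2 fold change 3.04, adjusted p = 0.028). Without tumor library 1 the median was −0.26 and 2 rose and 3 fell. The count depended on the tool: 7 of 14 markers with an adjusted p rose with DESeq2, and 4 rose and 1 fell with voom (median 1.13). The corneal and surface epithelium list had a median log2 CPM of 6.86 and 6.85 in wild type and of 1.84, 7 and 3.33 in the tumors, and the keratin gene Krt15, likewise chosen after its values were seen, was at 465, 498, 1.86, 598 and 11.2 FPKM in the same order. Of its 14 members Epcam alone rose (log2 fold change 2.04, adjusted p = 0.022) and 0 fell (0 and 0 adjusted over the list alone; median −0.90, adjusted p = 0.161), while 10 fell without tumor library 2 (median −3.97, adjusted p = 0.000939), 2 with DESeq2 and 5 with voom (median −2.89).

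**Figure D3:**
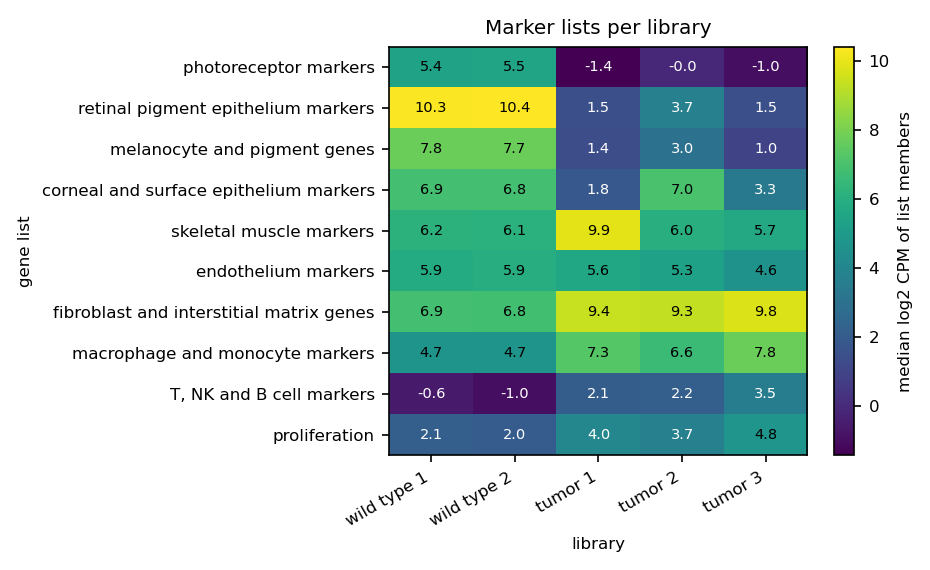
Median log2 CPM of the members of 10 gene lists in each of the 5 libraries, on a color scale from dark (low) to yellow (high). Skeletal muscle markers reach 9.92 in tumor library 1, and surface epithelium markers reach 7 in tumor library 2 against 1.84 and 3.33 in the other tumors.

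Other stromal lists were not called. Of 14 endothelium markers 3 fell and 0 rose (1 and 0 adjusted over the list alone; median −0.52, adjusted p = 0.0942). The sialoprotein gene Emcn had a log2 fold change of −1.55 (adjusted p = 0.02) and Vwf, the von Willebrand factor gene, one of −1.92 (adjusted p = 0.033), which did not pass without tumor library 2 (adjusted p = 0.055). Without tumor library 1, 5 endothelium markers fell and the list passed (adjusted p = 0.011), and 6 fell with DESeq2 and with voom. Of 13 smooth muscle and pericyte markers 3 fell and 0 rose (0 and 0 adjusted over the list alone), with a median of −0.13, a mean of 0.02 and adjusted p = 0.761. Myh11 and Myl9, a heavy and a light chain gene of smooth muscle myosin, had log2 fold changes of −2.17 (adjusted p = 0.035) and −1 (adjusted p = 0.044). Myh11 did not pass without tumor library 2 (adjusted p = 0.057) or 3 (adjusted p = 0.061), nor Myl9 without tumor library 1 (adjusted p = 0.086), with library size alone (adjusted p = 0.082) or with upper quartile factors (adjusted p = 0.064). Without tumor library 1, 2 and 3 in turn, 2, 1 and 1 smooth muscle markers rose and 2, 1 and 2 fell, and the median was 0.10 without tumor library 3. Over all 5 libraries, 3 rose with DESeq2 and with voom (median −0.32 with voom).

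Of 15 Schwann cell and neural crest markers S100b alone fell (log2 fold change −4.03, SE 1.04, adjusted p = 0.04) and 0 rose (0 and 0 adjusted over the list alone). The median was 0.90 and the mean 0.49, whereas camera put the list lower (adjusted p = 0.937). S100b did not pass without tumor library 1 (adjusted p = 0.061) or 2 (adjusted p = 0.073), 1 member rose with DESeq2, the median was 0.05 with voom, and 6 rose without tumor library 3, whose median log2 CPM for the list lay below the mean of the other tumors by a difference of −3.45. Red cell genes were lower: the Hba-a1 and Hba-a2 locus had a log2 fold change of −3.47 (adjusted p = 0.013), the beta-globin locus of −3.53 (adjusted p = 0.011) and Alas2 of −3.42 (adjusted p = 0.011).

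Glycolysis and hypoxia response genes went both ways, and camera called neither list. Of 18 glycolysis genes 4 rose and 4 fell (4 and 5 adjusted over the list alone; median −0.10, adjusted p = 0.668). The lactate exporter gene Slc16a3 rose by 3.50 (adjusted p = 0.0056) and Pfkfb4 by 1.65 (adjusted p = 0.01), while the phosphofructokinase gene Pfkl had a log2 fold change of −1.33 (adjusted p = 0.018), and 7 fell without tumor library 1 and with DESeq2 or voom (median −0.33 with voom). Of 30 oxidative phosphorylation genes 1 fell and 0 rose (0 and 0 adjusted over the list alone; median −0.31, adjusted p = 0.0628), the 1 being Sdha (log2 fold change −1.03, adjusted p = 0.035), which did not pass without tumor library 2 (adjusted p = 0.056) or 3 (adjusted p = 0.061). Without tumor library 1, the library with the skeletal muscle transcripts, 14 of the 30 fell (median −0.64, adjusted p = 3.85e-05), and camera also called the list without wild-type library 2 (adjusted p = 0.026). Over all 5 libraries, 5 of the 30 fell with DESeq2 and 7 with voom. Of 15 hypoxia response genes 3 rose and 3 fell (3 and 3 adjusted over the list alone), and 5 rose with voom. The prolyl hydroxylase gene P4ha1 rose by 1.69 (adjusted p = 0.0055) and Ankrd37 by 2.06 (adjusted p = 0.015), whereas the growth factor gene Vegfa had a log2 fold change of −1.85 (adjusted p = 0.0097). The median was −0.10, or 0.07 without tumor library 2, with a mean of 0.31, and the list passed by fry (adjusted p = 0.0186) and not by camera (adjusted p = 0.914).

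Lists tied to human uveal melanoma did not pass camera. Of 14 tested genes of G alpha q signalling and uveal melanoma drivers 3 rose and 3 fell (6 and 4 adjusted over the list alone and with voom; median 0.30, adjusted p = 0.679). The GTPase gene Arf6 rose by 1.11 (adjusted p = 0.014) and the kinase gene Prkcd by 2.18 (adjusted p = 0.017), and Rasgrp3, an exchange factor gene, had a log2 fold change of −2.90 (adjusted p = 0.0052). The recurrent human drivers Gnaq (log2 fold change 0.51, adjusted p = 0.063) and Gna11 (−0.05, adjusted p = 0.83), chosen after their values were seen, did not pass. Of the 4 genes higher in human class 2 tumors Ecm1 and Rab31 rose by 2.32 (adjusted p = 0.0094) and 2.47 (adjusted p = 0.019) and 0 fell (2 and 0 adjusted over the list alone; median 2.16, adjusted p = 0.246, fry adjusted p = 0.00569). Without tumor library 2 or with voom, 1 of them fell, and without tumor library 3, 3 rose. Of the 8 genes lower in class 2 tumors 1 rose and 2 fell (2 and 2 adjusted over the list alone; median 0.34, adjusted p = 0.937). Mtus1 and Id2 had log2 fold changes of −1.50 (adjusted p = 0.022) and −1.34 (adjusted p = 0.037), Lmcd1 rose by 1.8 (adjusted p = 0.012), and the Id2 call ended without tumor library 1 (adjusted p = 0.087), with 2 then rising and 1 falling; 2 rose and 3 fell without tumor library 3, and 2 rose and 2 fell with DESeq2 and with voom.

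Of 14 immediate early and stress genes 6 rose and 0 fell (6 and 0 adjusted over the list alone). The growth-promoting transcription factor gene Myc rose from 1.62 ± 0.278 to 21.6 ± 4.37 FPKM (log2 fold change 3.74, SE 0.25, adjusted p = 0.0036), and the stress factor gene Atf3 rose by 2.30 (adjusted p = 0.014). The list's median was 0.72 (adjusted p = 0.0559). It passed by fry (adjusted p = 0.0175) and by camera without tumor library 1 (adjusted p = 0.0115), tumor library 3 (adjusted p = 0.0258) or wild-type library 1 (adjusted p = 0.046), there were 4 rises and 1 fall without tumor library 2, and voom called 7 rises and 1 fall. In all, camera called 11 of 26 lists, 6 higher and 5 lower in tumors, fry called 16, and camera with an estimated correlation called 0. That setting also missed the simulated shifted list, but its genes were drawn independently. The called lists had estimated correlations from 0.0819 (fibroblast and interstitial matrix) to 0.815 (proliferation), so the simulation does not settle whether they would hold.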

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

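Voom with group weights, unnamed loci kept and DESeq2 without a wild-type library were chosen only after the results were seen. Called loci kept their direction in every setting in which they were called again. With RLE factors, upper quartile factors, library size alone, TMM without the eye and muscle genes, other filters, robust dispersion, DESeq2, limma-trend, voom or unnamed loci kept, 4675 to 7330 loci were called and 4522 to 5201 of the main 5201 among them. Lats2 passed with RLE factors (−0.65, adjusted p = 0.05), DESeq2 (−0.66, adjusted p = 0.015) and voom (−0.63, adjusted p = 0.016). Its log2 fold change ran from −0.81 to −0.52 over the 5 leave-one-out fits and passed without tumor library 2 (adjusted p = 0.017). That of Lats1 ran from −1.37 to −1.12. Lats1 did not pass in edgeR without wild-type library 1 (−1.37) or 2 (−1.13), where the spread between tumors alone sets the error.

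Over those fits the changed loci ran from 0 to 6144, the rises from 0 to 3032, the falls from 0 to 3112 and those past a log2 fold of 1 from 0 to 4930. The zeros are the fits with 1 wild-type library, where the spread between tumors alone sets the error. There DESeq2 called 2840 loci (1647 higher, 1193 lower) without wild-type library 1 and 2794 (1605 higher, 1189 lower) without library 2. An adjusted p under 0.01 left 1108 loci (577 higher, 531 lower, 1100 past a log2 fold of 1), and glmTreat left 1601 (906 higher, 695 lower), by construction. A replicate block on the numbers called 3067 loci (1706 higher, 1361 lower). Deviations of same-numbered libraries correlated at 0.01 and 0.03 across genes. The 2 wild-type libraries were so alike that these values cannot tell whether the numbers pair the libraries. For the lists, camera called 12 to 15 over the leave-one-out fits, 11 to 13 over 17 other settings and 0 with an estimated correlation, and fry called 16. The oxidative phosphorylation list passed with no filter (adjusted p = 0.048) and with unfiltered FPKM (adjusted p = 0.049), and the immediate early list with no filter (adjusted p = 0.039), DESeq2 (adjusted p = 0.048) and the block (adjusted p = 0.027). Of 76 named genes 66 to 76 kept their side of the threshold in each setting except those without a wild-type library, where 1 did with edgeR and 64 or 65 with DESeq2. Sox10 passed with voom alone (adjusted p = 0.042). At this depth, loci near 0 in a group give only a bound on the fold. Member counts of some lists also moved by over 1.5 times with limma-trend, other factors, a filter at 50 counts or the block, among them 7 T, NK and B cell rises with limma-trend without a filter and 3 lens falls with the block.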

Other observations

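All tests of explanations given here were chosen only after the results were seen, as were the genes named outside the rule.

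Several chemokine and matrix enzyme genes were picked from the large rises, with no list or test of either group. The monocyte chemokine genes Ccl2, Ccl7 and Ccl12 rose by 6.82 (adjusted p = 0.0062), 7.28 (adjusted p = 0.0072) and 5.49 (adjusted p = 0.0061), and the lymphocyte chemokine genes Cxcl13 and Cxcl10 by 7.12 (adjusted p = 0.0029) and 5.82 (adjusted p = 0.0056). Mmp13, a collagenase gene, rose by 6.72 (adjusted p = 0.01), the collagen crosslinking enzyme gene Lox by 5.62 (adjusted p = 0.004) to 303 ± 81.2 FPKM (SD, n = 3), and the collagen prolyl hydroxylase gene P4ha3 by 6.74 (adjusted p = 0.0091). The growth factor gene Nrg1 rose from 0.393 ± 0.11 to 13.2 ± 1.98 FPKM (log2 fold change 5.46, adjusted p = 0.0036). Mmp3, a matrix enzyme gene of the epithelial-mesenchymal transition list, had a log2 fold change of −2.84 that did not pass (adjusted p = 0.068).

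Some secretory and transport genes were likewise picked from the large falls. Ptgds, the prostaglandin D synthase gene, went from 25000 ± 1080 to 57.9 ± 46.1 FPKM (log2 fold change −8.70, adjusted p = 0.0083), and Ttr, the transthyretin gene, from 7420 ± 234 to 9.79 ± 10 FPKM (−9.51, adjusted p = 0.008). The lactate transporter gene Slc16a8 (−8.55, adjusted p = 0.0098), the bicarbonate transporter gene Slc4a5 (−7.99, adjusted p = 0.02), the potassium channel gene Kcnj13 (−8.36, adjusted p = 0.0097) and the thyroid hormone transporter gene Slco1c1 (−7.87, adjusted p = 0.0091) were lower too. The serotonin receptor gene Htr3a (−8.77, adjusted p = 0.004) and the thyrotropin receptor gene Tshr (−7.95, adjusted p = 0.0049) fell as well. Igfbp5, also abundant and secreted, was at 543 ± 20.8 FPKM in wild type and 290 ± 182 FPKM in tumors and did not pass (log2 fold change −0.85, adjusted p = 0.39). The cone genes Opn1mw and Arr3 were at 12.6 and 4.39 FPKM and at 20 and 7.08 FPKM in the wild-type libraries. They were picked for this difference, which was not tested, and cone genes as a group were not compared.

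Of 20 pigment genes 17 fell, and retinal pigment epithelium held in the wild-type libraries and lost from the tumors may account for part of this. Tyr, Dct, Pmel, Mlana and 6 further genes that this epithelium shares with melanocytes had a median log2 fold change of −8.48 (−9.77 to −6.93), against −1.8 (−2.15 to −1.77) for Sox10, Kit and Ednrb, which melanocytes make and this epithelium is taken to lack, a difference of 6.68. Sox10 did not pass, and its fold hides a spread between tumors. It was at 22.6%, 60% and 2.12% of the wild-type mean in tumor libraries 1, 2 and 3, against 0.195%, 0.448% and 0.0701% for Mlana. Other cells also make Sox10, Kit and Ednrb, so a loss of the pigment program in tumor cells stays open and was not tested. Tumor cells that lost this program and kept these genes would give such a difference too. The difference therefore cannot tell that loss from a loss of retinal pigment epithelium. A smaller share of all wild-type eye cells by 1 common factor would lower alike those markers that only these cells make, and the eye lists moved apart. The pigment median of −6.16 lay below the inner retina median of −1.41 by a difference of −4.75 (95% interval −6.92 to −0.675 over 10000 resamples of the genes), and the photoreceptor median of −6.46 by one of −5.05 (−6.77 to −3.25). On ratios of FPKM + 0.01 without tumor library 2, the pigment interval held 0 (−6.82 to 0.511) and the photoreceptor one did not (−5.99 to −2.12). The intervals treat genes as independent and do not measure the spread between tumors. Inner retina members also moved unlike each other, from a fold of 0.0265 (Slc6a9) to 5.80 (Kcnj10), with Sncg at 1.00. That list may therefore not track wild-type eye cells alone. The comparison cannot exclude a common factor, and losses that differ between cell types stay open as well.

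Interferon and antigen presentation genes rose, and more leukocytes in the tumors than in wild-type uvea could account for it. The median log2 fold change of 2.97 differed from the macrophage list's 3.40 by −0.43, with a 95% interval of −1.26 to 0.97 over 10000 resamples of the genes, which are not independent. The interval holds 0. Either an influx of leukocytes or an induction within resident or tumor cells could set the list's median above or below the macrophage median. The comparison therefore cannot tell these causes apart, wherever the interval lies. The abundant leukocyte gene Lyz2 was at 338 and 367 FPKM in wild type and at 2390, 1090 and 6470 FPKM in the tumors. Wild-type tissue expressed 20 of the 23 interferon genes and 15 of the 17 macrophage markers at 1 FPKM or more.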
